A study of Homo sapiens with 16 samples.

How the data were processed

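m6A-seq was done on poly(A) RNA of HEK293T cells of a single Cas9 clone, infected with lentivirus carrying a guide against METTL3, METTL14 or METTL16 or a non-targeting guide, and selected for 10 days with 10 µg/ml blasticidin and 100 µg/ml hygromycin. Each of the 4 genotypes has 2 input and 2 immunoprecipitated libraries, 16 samples in 8 groups. Per the labels the authors aligned the reads with STAR to GRCh38, and the peak caller, its filters and its annotation are not stated. The 6 deposited tables each compare 1 knockout pair of libraries (immunoprecipitated and input) with 1 control pair. Both METTL3 tables use control replicate 1, and the METTL14 and METTL16 tables use control replicate 2.

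The deposited tables give for each site a p-value of the peak, the site's enrichment as a ratio of immunoprecipitated over input signal computed by the authors, and the authors' log2 fold change of that enrichment between knockout and control. They also hold deposited scores, which are log10 of the p and of the adjusted p of the peak and of the difference. At the named sites the log10 adjusted p of the difference reached −434, and the log10 adjusted p of the peak was infinite at 1485 to 1936 sites per table. Small whole-number ratios among the log2 values point to a pseudocount. The direction of the log2 fold change is not stated and was read as knockout over control. No counts per library are given, so depth is unknown, and no interval that needs it was computed. Gene names and bases were compared with GENCODE release 29 on GRCh38, which held 93.7% of the gene names. MAT2A and GGCX, which overlap on opposite strands, hold nearly equal values, so reads appear to have been counted without regard to strand there. Other overlapping genes were not compared in this way. In all, 1157 sites (4.4%) share at least 50% of the shorter site with another gene's site.

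Sites of different tables were linked when they had the same gene and strand and overlapped by at least 50% of the shorter site, which gave 26373 sites over all tables. Links that would have joined 2 sites of a table were refused (1425). For each knockout a site was called when the authors' adjusted p was 0.05 or less with the same sign in both tables. These counts were set beside the number given by independent tables and beside 100 simulated sets of unchanged knockouts that share 1 control pair. The simulated tables hold no common shift. As the second test, limma 3.58.1 in R 4.3.3 was fitted to the log2 fold changes of all 6 tables, with missing sites left out and up to 3 residual degrees of freedom per site. The authors' test was also repeated on values centred on the table median, with the standard error that their p and log2 fold change imply. At sites without a change their log10 p was −0.0792, so the implied standard error becomes too small at sites with little change. Once a negative median is subtracted, such sites are readily called higher. The lone control was assumed to vary like a knockout library, which widens the standard error of each knockout, and it was taken to cancel in METTL16 minus METTL14. Benjamini-Hochberg adjustment covered the sites tested in each comparison. The fit was tested on simulated data with planted changes. A permutation of 2 against 2 samples cannot go below p 0.333, so none was made.

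The genes named are, for each knockout, the 10 largest mean decreases and 10 largest mean increases among called sites with 1 site per gene, all sites of METTL3, METTL14, METTL16 and MAT2A, and 2 to 4 examples of each list by size of change. Other names were chosen after their values were seen and are introduced so. There were 23 gene lists, tested in each knockout for the share of genes with a lower or a higher site against all other genes with a linked site (Fisher's exact test, two-sided, 126 tests, Benjamini-Hochberg over all of them), where at least 3 genes were measured. As further tests, list genes were compared with 10000 random lists matched on the number of sites, and their mean log2 fold change with random lists (63 tests), whose smallest p is 0.0002.

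Transcript regions and sequences were read from the annotation for the 91.4% of sites with at least 80% of their bases in 1 transcript. The midpoint of a site gave its region, with a window of 200 nt around the stop codon and exact Clopper-Pearson 95% intervals. DRACH and GGACT were counted per kb and compared between called and uncalled sites by two-sided permutation tests over sites within these libraries (100000 permutations, 12 tests, smallest p 1e-05). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

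Alternatives were an adjusted p of 0.01, a log2 change of at least 1 in size, centring of each table on its median, other rules for linking, filters on the peak, other models of the spread, a control without error, region by the 3′ end of the site, and each replicate left out. The calls, tests, gene lists, naming rule and most alternatives were set before the data were examined. Chosen after seeing the data were the filter on the peak's adjusted p, overlapping genes counted once, centred list tests, larger control spreads, the filter on peak enrichment for METTL16 minus METTL14, and leave-outs for shares, overlaps, lists, regions and motifs. Nothing was left out of the tables except sites without a partner in the other table of their knockout, which entered only the counts per table.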

Results

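N6-methyladenosine (m6A) was mapped by m6A-seq, in which RNA fragments bound by an m6A antibody are sequenced beside the unselected input RNA, in HEK293T cells, a human embryonic kidney line, that expressed Cas9. Cells of a single Cas9 clone were infected with lentivirus carrying a guide RNA against METTL3, METTL14 or METTL16, or a non-targeting guide as the control. There were 16 libraries in 8 groups of 2 replicates, an input and an immunoprecipitated group for each guide. The series asked which m6A each of these 3 methyltransferases makes. The deposited tables list m6A sites and their log2 fold change between 1 knockout pair of libraries and 1 control pair, so a positive value is read here as more m6A signal in the knockout. The tables hold 13367 and 14149 sites for the METTL3 replicates, 17297 and 15886 for METTL14, and 16874 and 17645 for METTL16. Between 29.9% and 33.8% of the sites of a table had a peak adjusted p above 0.05. The tables hold no counts per library, so the depth of each library is unknown, as is the RNA level of each targeted gene. The loss of the 3 enzymes therefore cannot be checked from these tables. Below, a site is called lower or higher when the authors' adjusted p was 0.05 or less with the same sign in both replicate tables (n = 2 knockout replicates against 1 control replicate), and the error after ± is the limma standard error. All positions are on GRCh38.

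**Figure D1:**
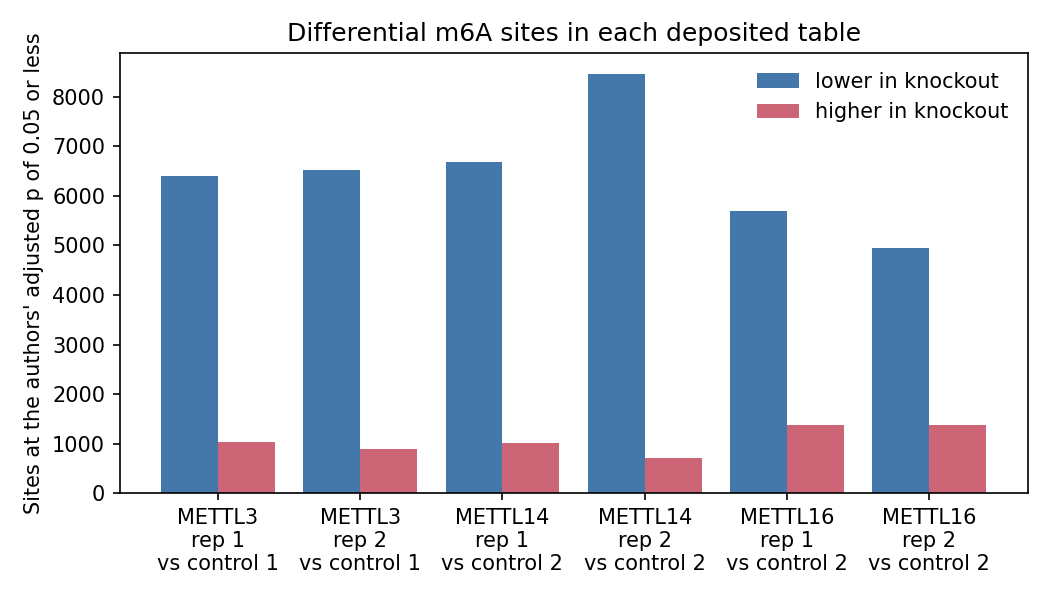
Number of sites at the authors' adjusted p of 0.05 or less (vertical axis) in each of the 6 deposited tables (horizontal axis, knockout replicate against its control replicate), with lower and higher sites as separate bars. Lower sites run from 4940 to 8459 and higher sites from 715 to 1377, without centring of the tables on their medians.

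Transcripts of the targeted genes carried m6A sites of their own. In METTL3 knockout cells the coding-sequence site of METTL3 (chromosome 14, 21503245 to 21503393) fell by 3.72 ± 0.89 on the log2 scale. The same site was called lower in METTL16 knockout cells at −1.09 ± 0.89 and was not called in METTL14 knockout cells at −0.42 ± 0.89, a value that turns positive (1.08) once each table is centred on its median. The METTL14 site at the stop codon (chromosome 4, 118710054 to 118710504) was called lower after METTL3 knockout at −3.53 ± 0.66 and after METTL14 knockout at −1.38 ± 0.66, although centring turned the latter to 0.12. After METTL16 knockout it was not called, at −1.27 ± 0.66. In METTL16, the 3′ UTR site (chromosome 17, 2416234 to 2416413) was called lower after METTL14 knockout at −7.01 ± 1.84 and after METTL16 knockout at −4.40 ± 1.84. The METTL16 coding-sequence site (2419889 to 2420518) was called lower at −1.57 ± 0.50 after METTL3 knockout, where centring turned it to 0.025, and at −1.90 ± 0.50 after METTL14 knockout. It was not called after METTL16 knockout, at 0.46 ± 0.50. The METTL3 5′ UTR site (chromosome 14, 21511137 to 21511316) was called lower after METTL14 knockout at −4.11 ± 4.49 and not called after METTL16 knockout at −2.86 ± 4.49, and the METTL16 5′ UTR site was not called after METTL3 knockout at 0.78.

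The METTL3 comparison asks which sites lose m6A without this enzyme. The KLF4 coding-sequence site (chromosome 9, 107487305 to 107487543) fell by 9.73 ± 0.61, the largest decrease, and the IRS2 site fell by 9.13 ± 1.38. The other 8 of the 10 largest decreases, in MIR600HG, ACSF3, RCC1L, ZDHHC8, APEX2, SNAI3, FBXL18 and SLC27A3, lay between −8.74 and −8.18. In the other direction PHAX, an adaptor of small nuclear RNA export, rose by 9.04 ± 0.37 and ANO6 by 8.27 ± 0.74. The other 8 of the 10 largest increases, in ATL2, SZRD1, HSDL1, DYNLRB1, C9orf16, STK4, PDS5B and CDK5RAP3, lay between 7.39 and 6.28, and none of these 10 sites was listed in both tables of METTL14 or of METTL16 knockout. Of 11318 sites found in both METTL3 tables, in 7043 genes, 4997 in 3728 genes were lower, 343 in 325 genes were higher and 254 changed in opposite directions. The median site stood at −1.66, the lower sites at −2.60 and the higher sites at 2.03. Lower sites made up 87.0% ± 1.26 (SD, n = 2 tables) of the significant sites of a table. The share was 72.5% when the same calls, made against 0, were re-signed relative to the table median, which was −1.48 and −1.70 over these sites. Sites near 0 were not called and so do not enter that share, which favours lower sites. Tested again relative to the table median, 1409 sites were lower and 1797 higher in both tables. Subtracting the median sets this balance in large part, and whether m6A fell as a whole stays open. The implied standard error is too small at sites with little change, which can inflate the higher count. With replicate 2 alone 556 sites were higher, and with replicate 1 alone 734. With independent tables, 3424.9 lower and 36.1 higher sites would be shared by chance, but both tables share 1 control pair. Unchanged knockouts simulated against a shared control gave medians of 1122 lower and 1119 higher sites, the latter above the 343 observed. The simulation holds no common shift, so these counts do not tell an offset from a loss of m6A. Relative to the table median, 3206 sites were called with the same sign, against 2144 to 2366 simulated. With a control spread 1.5 times that of a knockout library the simulation gave 3162 to 3394. Under limma, with the lone control assumed to vary like a knockout library, 0 sites were lower and 0 higher after adjustment, with 2275 of 11318 at an unadjusted p under 0.05. In simulated data that fit recovered 0% of changes of −6 or 6, planted at 50 sites each among 11318. Recovery with as many changed sites as were called here was not simulated. The 0 of limma therefore does not show that sites were unchanged.

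Genes of lists fixed before the data were examined were tested for their count of lower and higher members, and the higher members named here were chosen after their values were seen. In METTL3 knockout cells, UQCR11 at 4.41 ± 0.29, SDHD at 4.21 ± 1.86, NDUFS5 at 3.82 ± 0.35, NDUFB10 at 3.39 ± 0.48 and NDUFB8 at 3.27 ± 0.25 rose, 5 of the 7 measured nuclear-encoded respiratory chain genes (adjusted Fisher's exact p 0.000167). Immediate early genes, which are induced within minutes of a stimulus, split in both directions. FOS at 3.22 ± 0.35, FOSB at 1.40 ± 0.42, JUN at 1.21 ± 0.22 and DUSP1 at 1.04 ± 0.31 were among 10 of 26 genes with a higher site, against 4.5% of other genes (adjusted Fisher's exact p 1.33e-05). In the same list KLF4 at −9.73, KLF2 at −6.73 and FOSL2 at −6.45 were among 11 genes with a lower site (7 after centring, against 13 higher), and the list mean did not pass its test against 10000 random lists (adjusted p 0.272). Of 11 splicing factors, SNRPD2 at 3.67 ± 0.59, SRSF6 at 2.83 ± 0.23, SRRM2 and U2AF2 had a higher site (adjusted Fisher's exact p 0.0143), while SRSF1 at −2.64 ± 0.82 was among 4 with a lower site. Chromatin modifiers were lower in 36 of 42 genes, against 3728 of all 7043 genes (adjusted Fisher's exact p 0.000348, and 0.0392 against genes matched on their number of sites). They included the demethylases KDM4B at −5.12 ± 0.52 and KDM5B at −5.12 ± 1.66, and the acetyltransferase EP300 at −4.86 ± 2.27. Centring reversed 6 of the 36 chromatin genes. By sign relative to the median 26 had a lower and 12 a higher site, against 35.8% and 15.0% of other genes. The mean of the chromatin list did not pass its test against random lists (adjusted p 0.976).

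The METTL14 comparison asks the same of the partner of METTL3 in the writer complex. HOXA11-AS, an antisense noncoding RNA of the HOXA cluster, fell by 8.25 ± 0.77, and KEAP1, an adaptor of the ubiquitin ligase that degrades NRF2, fell by 7.76 ± 0.38. The other 8 of the 10 largest decreases were in IGSF3, FBXO22, C2orf88, IL17RA, ZNF524, METTL16, RASSF7 and ARTN, between −7.92 and −6.83. Among the 10 largest increases, CDCA2, PWP2, ADI1, STAG2, MAT2A, GGCX, DDX19A, MSMO1 and DLX6 rose by 4.96 to 3.33. ADI1, an enzyme of methionine salvage, rose by 4.58 ± 0.23 and had also risen by 3.28 ± 0.23 after METTL3 knockout. Of 14216 sites found in both tables, in 8319 genes, 5495 in 4054 genes were lower, 209 in 192 genes were higher and 397 went opposite ways. The median site stood at −1.61, the lower sites at −2.69 and the higher sites at 1.05. Lower sites made up 89.5% ± 3.85 (SD, n = 2 tables) of the significant sites. The share was 74.1% when the same calls were re-signed relative to table medians of −1.42 and −1.58, which favours lower sites. Tested relative to these medians, 1603 sites were lower and 1572 higher, the latter inflated where the implied standard error is too small. Chance with independent tables gives 3718.3 lower and 24.2 higher sites, and simulated unchanged knockouts with a shared control gave medians of 1325 and 1318.5, the latter above the 209 observed. With replicate 2 alone 508 sites were higher, and with replicate 1 alone 676. Under limma 0 sites were lower and 0 higher, with 2357 of 14216 at an unadjusted p under 0.05. That fit recovered 0% of simulated changes of −6 or 6, planted at 50 sites each, and denser changes were not simulated.

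In METTL14 knockout cells a larger share of immediate early genes than of other genes again had a higher site. FOSB at 1.74 ± 0.42, JUN at 1.34 ± 0.22, EGR1 at 1.07 ± 0.20 and DUSP1 at 1.05 ± 0.31 were among 7 of 26 genes with a higher site, against 2.2% of other genes (adjusted Fisher's exact p 8.99e-05). In 14 genes of the list a site was lower (4 after centring, against 10 higher), including KLF4 at −6.19 ± 0.61 and ZFP36L1 at −5.31 ± 1.08. Of 15 splicing factors, SNRPD2 at 3.15 ± 0.59, SRSF8, SRRM2 and U2AF2 had a higher site (adjusted Fisher's exact p 0.00432, and 0.0998 with signs taken relative to the median), against 7 with a lower site, or 2 after centring. Chromatin modifiers were lower in 34 of 43 genes, against 4054 of all 8319 genes (adjusted Fisher's exact p 0.00129), with TET3 at −5.82 ± 0.97, KDM3B at −5.82 ± 0.36 and CHD7 at −5.53 ± 2.48. Against genes matched on their number of sites the p of this list was 0.109, and its mean did not pass its test against random lists (adjusted p 0.945). Centring reversed 8 of the 34 genes, and by sign relative to the median, which was not tested site by site, 25 of the 43 had a lower and 19 a higher site.

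The METTL16 comparison asks which sites need this enzyme, which is outside the METTL3 and METTL14 complex and methylates U6 small nuclear RNA and hairpins of MAT2A mRNA. The MAT2A 3′ UTR site, whose bases GGCX shares, fell by 6.03 ± 2.05, and CTC-338M12.4, a noncoding transcript, fell by 7.11 ± 1.36, the largest decrease. The glycolytic enzyme gene ALDOA fell by 6.48 ± 1.51, and the rest of the 10 largest decreases, in HAPLN4, MEGF6, GPATCH2, SEC23IP, RHPN1, CENPL and CYP2U1, lay between −6.64 and −6.0. C1orf116 rose by 6.08 ± 0.79, and FAM13B, TTC23, SLF1, FBXL6, SOWAHA, CASZ1, PRX, BTNL9 and PPP1R16A rose by 4.78 to 3.62. Of 14755 sites found in both tables, in 8507 genes, 3066 in 2518 genes were lower, 405 in 380 genes were higher and 485 went opposite ways. The median site stood at −1.0, the lower sites at −2.16 and the higher sites at 0.87. Lower sites made up 79.4% ± 1.57 (SD, n = 2 tables) of the significant sites. The share was 72.1% when the same calls were re-signed relative to table medians of −0.83 and −1.0, which favours lower sites. Tested relative to these medians, 893 sites were lower and 2037 higher, the latter inflated where the implied standard error is too small. With replicate 2 alone 4814 sites were lower and 1100 higher, and with replicate 1 alone 5508 and 1088. Chance with independent tables gives 1797.1 lower and 81.1 higher sites, and simulated unchanged knockouts with a shared control gave medians of 1331.5 and 1333.5, the latter above the 405 observed. The simulation holds no common shift, so these counts do not tell an offset from a loss of m6A. Under limma 0 sites were lower and 0 higher, with 1313 of 14755 at an unadjusted p under 0.05. That fit recovered 0% of simulated changes of −6 or 6, planted at 50 sites each, and denser changes were not simulated.

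In METTL16 knockout cells the cell cycle genes E2F3 at 1.19 ± 1.32, MCM2 at 1.10 ± 1.11, MCM3 at 0.86, CDKN2C, MKI67 and CENPF had a higher site, 6 of 17 genes (adjusted Fisher's exact p 0.00129), while 8 of the 17 had a lower site (3 after centring, against 9 higher). Immediate early genes were higher in 7 of 25, with IER3 at 0.70, DUSP1 at 0.54 ± 0.31, FOSB at 0.52 ± 0.42 and EGR1 at 0.47 ± 0.20, against 4.4% of other genes (adjusted Fisher's exact p 0.00129). In 7 genes of that list a site was lower (3 after centring, against 12 higher), such as ZFP36L2 at −3.65 ± 2.33. FOSB, JUN, EGR1, DUSP1 and IER2 had a higher site in all 3 knockouts, of which METTL14 and METTL16 share a control, so that their calls are not independent. The median immediate early gene was still below 0, at −0.39, −0.95 and −0.15 after METTL3, METTL14 and METTL16 knockout, against −1.69, −1.63 and −1.0 in other genes. The same held for splicing factors, at −0.95 after METTL3 and −0.63 after METTL14 knockout, and for cell cycle genes after METTL16 knockout, at −0.48. Chromatin modifiers were lower in 27 of 43 genes, against 2518 of all 8507 genes (adjusted Fisher's exact p 0.000206, and 0.0479 against matched genes), led by TET2 at −4.73 ± 1.65, TET1 at −3.70 ± 0.34 and KMT2C at −3.59 ± 0.95. Centring reversed 4 of the 27. By sign relative to the median 18 had a lower and 9 a higher site, against 23.4% and 8.7% of other genes. The mean of the chromatin list did not pass its test against random lists (adjusted p 0.995).

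The remaining lists passed no Fisher's exact test of their count of lower or higher genes over 126 tests, and their counts are given in the order METTL3, METTL14, METTL16. Writer complex genes were lower in 8 of 8, 7 of 8 and 2 of 8, with WTAP at −2.95 ± 1.15 after METTL3 knockout and −3.43 ± 1.09 after METTL14 knockout, and a ZC3H13 site higher at 0.79 ± 0.36 after METTL16 knockout. Other N6-adenosine methyltransferase genes were lower in 2 of 3, 4 of 4 and 3 of 4, including PCIF1 at −5.17 ± 0.60 after METTL14 knockout and METTL4 at −5.80 ± 1.61 after METTL16 knockout. Eraser and reader genes were lower in 4 of 6, 5 of 9 and 1 of 10, with YTHDC1 at −4.09 ± 0.42 after METTL14 and −1.61 ± 0.42 after METTL16 knockout. In the methionine cycle 2 of 4, 3 of 7 and 4 of 6 genes were lower and 2, 2 and 0 higher, the latter MAT2A and ADI1. U6 snRNP and processing genes were lower in 5 of 6, 6 of 7 and 5 of 6, with CPSF7 at −4.81, −4.22 and −1.41 (± 0.54). Translation initiation genes were lower in 4 of 8, 3 of 8 and 1 of 8 and higher in 2 of 8 each time, EIF3I among them at 5.02 ± 0.25 after METTL3 knockout. Ribosomal protein genes were lower in 4 of 6, 2 of 6 and 2 of 7, and RPL7L1 rose by 5.23 ± 0.35 after METTL3 knockout and by 2.44 ± 0.35 after METTL14 knockout. ZNF genes were lower in 171 of 328, 202 of 391 and 132 of 396, with ZNF384 at −7.58 ± 0.83 after METTL3 knockout. After METTL16 knockout 7 of the 396 ZNF genes were higher, against 20.3 in lists matched on their number of sites (adjusted p 0.0108, and 0.0641 by Fisher's exact test). Histone genes were lower in 1 of 5, 2 of 5 and 2 of 6, H2AFJ each time at −3.41, −2.49 and −1.10 (± 0.48). Splicing factors in METTL16 knockout cells were lower in 5 and higher in 3 of 15. Cell cycle genes were lower in 11 of 15 and 11 of 19 after METTL3 and METTL14 knockout, and higher in 3 and 0.

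p53 and DNA damage genes were lower in 5 of 16, 9 of 21 and 7 of 21, with BRCA1 at −5.54 ± 1.20 after METTL16 knockout. Stress response genes were lower in 12 of 20, 13 of 23 and 7 of 21, with ATF5 at −4.44 ± 0.92 after METTL14 and −4.71 ± 0.92 after METTL16 knockout. Genes of double-stranded RNA sensing were lower in 4 of 9, 5 of 13 and 5 of 14, with ISG15 at −7.05, −5.42 and −3.82 (± 1.39). Long noncoding RNAs were lower in 2 of 7, 4 of 10 and 2 of 10, and a NORAD site was higher each time at 0.76, 0.68 and 0.67 (± 0.41). Wnt, Notch, Hedgehog and TGF-beta genes were lower in 26 of 37, 28 of 41 and 21 of 43, with CTNNB1 at −4.32 ± 2.07 and FZD7 at −4.41 ± 0.28 after METTL3 knockout. After METTL14 and METTL16 knockout the respiratory chain list had 1 of 6 and 1 of 5 genes lower and 1 and 0 higher, the latter NDUFB10 at 2.60 ± 0.48. Kidney markers were lower in 1 of 3, 2 of 5 and 2 of 5, SLC5A2 each time, and neuronal markers in 1 of 6, 3 of 6 and 0 of 6, with GAP43 higher at 4.69 ± 0.35 after METTL3 knockout. Only 1, 1 and 2 haematopoietic markers were measured, with 0 called and no test, and 0 mitochondrially encoded genes were measured. Adjusted over the list alone, limma called 4 sites of the respiratory chain after METTL3 knockout, 2 of the U6 list after METTL3 and after METTL14 knockout, 2 of the immediate early genes after METTL14 knockout, and 0 or 1 in every other list and knockout. With the signs of calls taken relative to the table median, a step that does not test the difference from it, the balance turned from lower to higher among erasers and readers and translation initiation genes after METTL3 and METTL14 knockout, writer genes after METTL16 knockout, cell cycle genes after METTL3 knockout, and p53 genes after METTL3 and METTL14 knockout. The same turn was seen for U6 genes after METTL3 knockout, long noncoding RNAs after METTL14, ribosomal proteins after METTL14 and METTL16, and histones and splicing factors after METTL16 knockout. Of 63 tests of a list's mean log2 fold change against random lists 12 passed. After METTL3 knockout these were the respiratory chain (mean 2.00, adjusted p 0.0126), and, each at an adjusted p of 0.0364, methionine cycle genes (1.35), splicing factors (−0.15) and neuronal markers (0.55), where random lists averaged −1.72 to −1.69. After METTL14 knockout they were other N6-adenosine methyltransferases (−4.52, adjusted p 0.0126), and at 0.0364 splicing factors (−0.68), immediate early genes (−0.93) and the respiratory chain (−0.03), against −1.71 to −1.70. After METTL16 knockout they were immediate early genes (−0.31, adjusted p 0.0364), cell cycle genes (−0.25, 0.0378), ZNF genes (−1.22, 0.0435) and other N6-adenosine methyltransferases (−2.89, 0.0493), against −1.06 to −1.05. The last of these lists has 4 measured genes, and the targeted gene METTL16 is among them.

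METTL16 and METTL14 knockout cells were compared directly, since both were set against the same control pair, which was taken to cancel in the difference. Only 2108 sites had identical start and end in all 4 tables, against 13218 linked. At the others the control may cancel only in part. The MAT2A 3′ UTR site (ENSG00000168906.12, chromosome 2, 85544566 to 85545161) differed by −10.21 ± 1.67 (limma p 0.00475, adjusted 0.249). In the authors' deposited table for each replicate, the MAT2A site changed by 5.43 and 5.31 after METTL3 knockout, 5.39 and 2.98 after METTL14 knockout, and −7.94 and −4.11 after METTL16 knockout. The means of 5.37, 4.19 and −6.03 (± 2.05) correspond to 41.4-fold, 18.2-fold and 0.0154-fold of the control. A GGCX site overlaps it on the other strand (85544720 to 85545169), with nearly the same values, so the reads could belong to either gene. The METTL16 coding-sequence site differed by 2.36 ± 0.41 (limma p 0.00568, adjusted 0.251). Across 13218 sites limma called 0 lower and 0 higher in METTL16 than in METTL14 knockout cells, with 1727 at an unadjusted p under 0.05. On simulated data this comparison recovered 36.2% of changes of −6 and 30.3% of changes of 6.

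**Figure D2:**
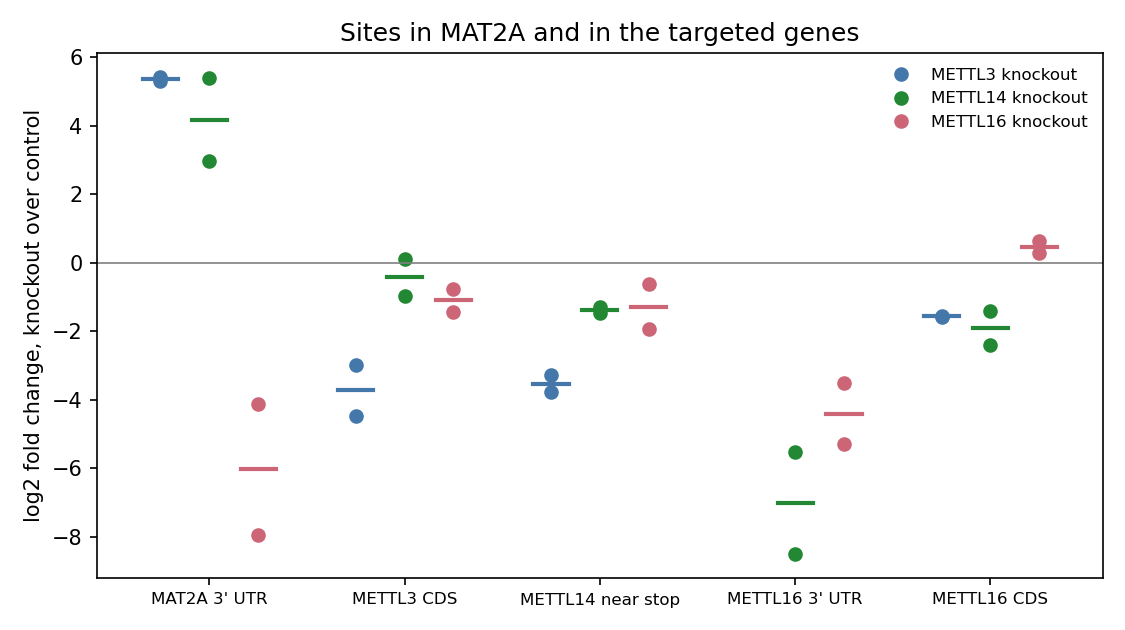
Log2 fold change, knockout over control (vertical axis), at 5 sites of MAT2A, METTL3, METTL14 and METTL16 (horizontal axis); each point is 1 replicate table, coloured by knockout, short lines are means and the long line marks 0. In the authors' deposited table for each replicate the MAT2A 3′ UTR site lies at 5.43 and 5.31 for METTL3, 5.39 and 2.98 for METTL14, and −7.94 and −4.11 for METTL16, while centring turns the METTL14 site in METTL14 and the METTL16 coding-sequence site in METTL3 knockout above 0.

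Sites lower in several knockouts were counted where all tables of the pair listed the site. VPS13D, TRIM25, YTHDF1, ZC3H13 and SRSF1, chosen after their values were seen, were among 98 genes' sites that were lower after METTL3 and METTL14 knockout and higher after METTL16 knockout, against 114.7 if calls were independent, although METTL14 and METTL16 share a control, which makes opposite calls rarer. On centring YTHDF1 and ZC3H13 turned positive after METTL3 (0.77 and 0.56) and METTL14 knockout (0.32 and 0.14). METTL3 and METTL14 knockout cells, which were set against different control replicates, shared 3166 lower sites of 9324, where independence gives 2243.2, and 104 higher sites, where it gives 4.7. METTL3 and METTL16 knockout cells shared 1521 lower sites against 1213.5, or 61.1% of those lower in METTL16. Independence takes every site as equally likely to be called. Lower sites were longer than uncalled ones, with medians of 389 against 240 nt for METTL3, 383 against 181 nt for METTL14 and 386 against 210 nt for METTL16. How far unequal chances of a call raise these overlaps was not computed. METTL14 and METTL16 knockout cells shared 2072 of 13218 against 1206.4, but they also share a control. Simulated unchanged knockouts with that control shared a median of 578.5, from fewer lower sites each, and the covariance of the knockout means was 0.82 against 1.59 simulated, so the overlap was not shown to exceed what the control gives. Calls from 1 replicate alone raised the overlap of METTL16 with METTL3 to between 2859 and 2923 and with METTL14 to between 3559 and 3881, while the ratios to independence fell, to 1.2 and 1.13 with METTL3 and to 1.39 and 1.4 with METTL14. Over the 9069 sites listed in all 6 tables, 1242 were lower and 31 higher in all 3 knockouts, 1872 were lower after METTL3 and METTL14 knockout but not METTL16, and 455 were lower after METTL16 knockout alone. Across sites, which are not independent replicates, the mean log2 fold changes of METTL3 and METTL14 correlated at r 0.414, METTL3 and METTL16 at 0.126, and METTL14 and METTL16 at 0.387. The shared control alone gave 0.666 for the last pair in simulation, a value that the assumed equal spreads set. METTL3 shares no control with METTL14, so 0 was taken for unchanged knockouts of that pair and was not simulated.

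Lower and higher sites fell in different parts of transcripts. After METTL3 knockout 29.4% (exact 95% interval 28.1 to 30.7) of 4746 lower sites were within 200 nt of a stop codon, against 8.1% (5.4 to 11.6) of 332 higher sites and 20.0% (18.9 to 21.1) of 5429 uncalled sites. The higher METTL3 sites, FOS, FOSB and JUN among them, were in 5′ UTRs in 28.3% (23.5 to 33.5) of cases, against 3.5% of the lower sites and 7.7% of the uncalled sites. After METTL14 knockout 28.6% (27.3 to 29.8) of lower, 16.7% (11.8 to 22.5) of higher and 21.0% (20.1 to 21.9) of uncalled sites were near a stop codon, and 17.2% (12.3 to 23.0) of higher sites were in 5′ UTRs. Placed by their 3′ end instead of their midpoint, 11.4% (8.2 to 15.4) of higher METTL3 sites and 7.4% (4.2 to 11.8) of higher METTL14 sites were in 5′ UTRs, against 5.1% and 4.8% of uncalled sites. After METTL16 knockout the shares near a stop codon were 25.3% (23.8 to 27.0) of lower, 29.1% (24.6 to 33.9) of higher and 23.6% (22.7 to 24.4) of uncalled sites. Among uncalled METTL16 sites with a peak adjusted p of 0.05 or less it was 26.3% (25.3 to 27.4), so the lower sites were not set apart from these. With that filter the share was 22.0% (20.5 to 23.4) of uncalled METTL3 sites and 23.2% (22.0 to 24.5) of uncalled METTL14 sites. By the 3′ end 20.6% (19.4 to 21.7) of lower and 11.1% (8.0 to 15.0) of higher METTL3 sites were near a stop codon, and the METTL14 intervals overlapped, at 19.6% (18.6 to 20.7) and 16.7% (11.8 to 22.5). By the 3′ end the order of lower and higher METTL16 sites turned, at 19.4% (18.0 to 20.9) and 16.6% (13.0 to 20.7). The intervals cover counting error over sites only.

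**Figure D3:**
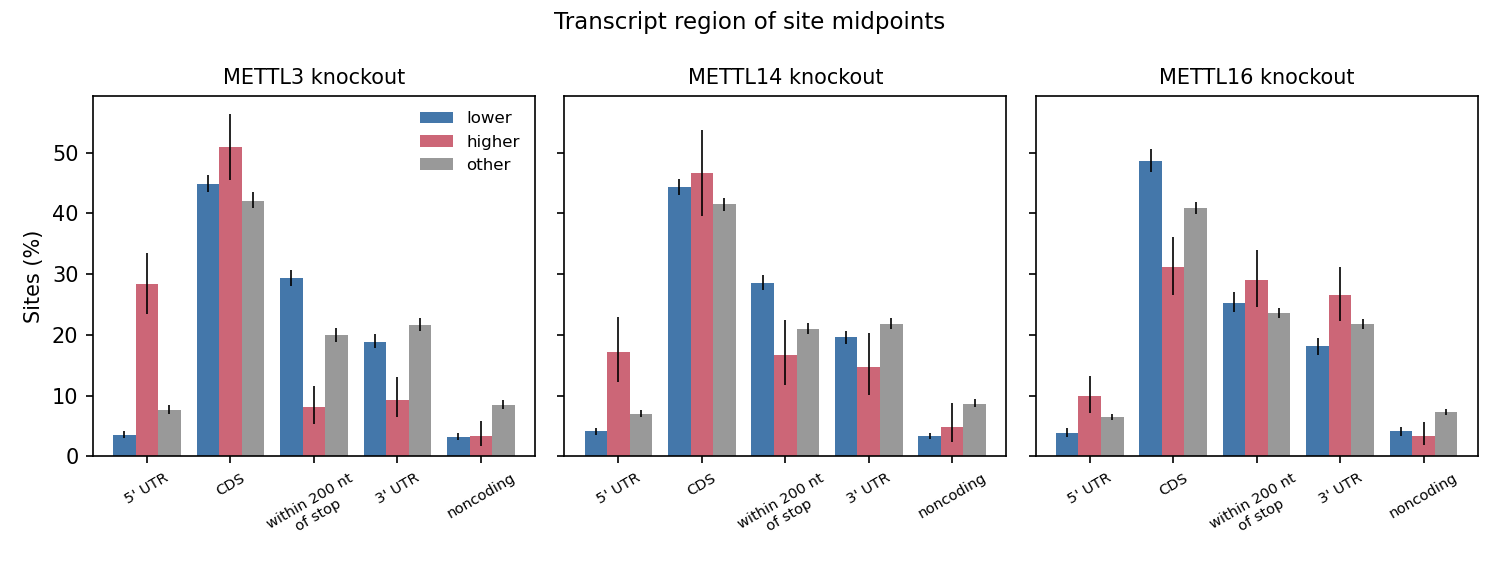
Percent of site midpoints (vertical axis) in 5 transcript regions (horizontal axis) for sites called lower, called higher or neither (other), in a panel per knockout; error bars are exact 95% intervals over sites. Near the stop codon lower sites stand at 29.4%, 28.6% and 25.3% for METTL3, METTL14 and METTL16 and higher sites at 8.1%, 16.7% and 29.1%, and in METTL16 knockout 48.6% of lower and 31.2% of higher sites were in coding sequence.

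DRACH, the core m6A consensus, was counted per kb of each site. Lower sites after METTL3 knockout had a median of 22.22 copies against 23.7 in the 2812 sites called in neither table, the comparison set of this paragraph, a difference of −1.47 (adjusted permutation p 1.7e-05). The differences were −0.91 for METTL14 (adjusted permutation p 0.0254) and −0.96 for METTL16 (adjusted permutation p 0.00693). Higher sites had smaller medians still, at 19.87, 21.69 and 21.43 for METTL3, METTL14 and METTL16, against 22.22, 22.42 and 22.85 in lower sites. A smaller density than in uncalled sites was thus not particular to lower sites, and higher sites were not tested. The differences from uncalled sites are those of lower sites throughout. These differences rested on single replicates in part, since the METTL3 difference was −0.83 without replicate 1 (permutation p 0.003), the METTL14 difference was 0.05 without replicate 1 (permutation p 0.919) and the METTL16 difference −0.30 without replicate 2 (permutation p 0.227). Among sites with a peak adjusted p of 0.05 or less in both tables the differences were larger, at −2.02, −2.13 and −1.39 for METTL3, METTL14 and METTL16 (each at an adjusted permutation p of 1.7e-05). Lower sites were also longer, with medians of 389, 383 and 386 nt against 240, 181 and 210 nt. GGACT, the commonest DRACH form at m6A sites, occurred in 54.3% of lower and 41.3% of the other METTL3 sites, in 53.6% and 35.0% for METTL14, and in 50.4% and 37.1% for METTL16. Among sites with a peak adjusted p of 0.05 or less in both tables the shares were closer, at 55.9% and 54.4%, 54.6% and 48.7%, and 51.2% and 49.6%. Its mean density was nevertheless lower in the lower sites, at 1.98, 1.96 and 1.77 copies per kb against 2.27, 2.15 and 2.09. Higher sites held GGACT in 40.1%, 50.5% and 56.9% of cases, at means of 1.57, 1.69 and 2.26 copies per kb.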

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

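The tests of few reads, of GGCX reads and of a control with a larger spread were chosen only after the result was seen; the tests of DRACH density and of an offset were written beforehand.

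MAT2A encodes the enzyme that makes S-adenosylmethionine, the methyl donor of m6A. Its 3′ UTR site stood at 5.37 after METTL3, 4.19 after METTL14 and −6.03 after METTL16 knockout, and every replicate of METTL16 moved against every replicate of the other two. GGCX, on the opposite strand of the same bases, stood at 5.49, 4.18 and −5.90. The remaining sites with this pattern were in genes chosen after their values were seen. DEGS1 stood at 1.77, 0.88 and −1.47, IP6K2 at 1.47, 0.65 and −0.92, and KLHL15 at 0.58, 0.91 and −0.59. These 5 sites were the only ones higher after METTL3 and METTL14 and lower after METTL16 knockout among 9069, where independent calls give 19.9, a number that the control shared by METTL14 and METTL16 makes too high. The difference between METTL16 and METTL14 was tested with limma and did not pass adjustment for MAT2A (−10.21 ± 1.67, adjusted p 0.249), DEGS1 (−2.35 ± 0.63, adjusted p 0.314), IP6K2 (−1.57 ± 0.44, adjusted p 0.323) or KLHL15 (−1.49 ± 0.23, adjusted p 0.246). The difference from METTL3, which has another control, was not tested.

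Between METTL14 and METTL16, 13 sites were higher in both METTL14 tables and lower in both METTL16 tables, where independent calls give 37.0, and 130 sites were lower in METTL14 and higher in METTL16, where they give 141.9. The shared control makes opposite calls rarer than independence gives, and the number it gives was not computed.

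For the MAT2A site, the tables argue against counting chance in a site with few reads. The highest log10 adjusted p over the 6 tables was −26.8, below 0.05 divided by the number of sites, a bound set after the value was seen because the pattern itself needs a call in every table. These p compare single library pairs, so variation between libraries stays open. Reads of GGCX cannot be told apart from those of MAT2A, because the values listed for the genes differ by at most 0.15 in any table. A biological explanation was not tested: METTL16 methylates hairpins of the MAT2A 3′ UTR, and loss of METTL3 or METTL14 may leave more signal there. The MAT2A site holds 4 copies of TACAGAGAA, the METTL16 target sequence, and no other site searched held more than 1. Levels of MAT2A RNA, which METTL16 controls, are not in the tables, and a change in them stays open as well.

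Most called sites were lower after METTL16 knockout, 3066 against 405, although METTL16 is not part of the METTL3 and METTL14 complex. Loss at DRACH sites of that complex could not be tested as planned: the METTL16 tables differed by −0.13 and 0.0 between the upper and lower terciles of DRACH density, but METTL14 itself gave 0.21 and −0.10. METTL3 gave 0.27 and −0.26. With peaks at an adjusted p of 0.05 or less in both tables, a filter chosen after the data were seen, METTL16 gave −0.115 and −0.19. With the same filter METTL14 still gave 0.3 and −0.125, and METTL3 0.26 and −0.27. An offset between control 2 and the METTL16 libraries could explain the direction, and centring removes the direction of an offset and of a broad loss alike. After centring, 2930 sites were called with the same sign in both tables, above the highest simulated count of 2769, which was the outcome named beforehand against an offset alone. That bound is simulated with a control that varies like a knockout library, which no table measures, so it excludes nothing by itself. With a control that varies more, the simulated counts were 3171 to 3415. The replicate r of 0.379, below the 0.498 simulated, cannot decide how much the control varies, because few reads could lower it too. Only 5133 METTL16 sites had identical start and end in both tables, against 14755 linked. At the others the control may be shared only in part, which could lower r as well. The retest also uses the implied standard error, which is too small at sites with little change. Such sites turn higher when a negative median is subtracted, and 2037 of the 2930 calls were higher. These values therefore do not decide whether an offset is the whole cause. A role of METTL16 at these sites, direct or through MAT2A and the methyl donor, stays open as well and was not tested.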

How the results depend on the processing

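The peak adjusted p filter, overlapping genes counted once, centred list tests, the peak enrichment filter for METTL16 minus METTL14 and leave-outs for overlaps, lists, regions, shares and motifs were chosen only after the result was seen; the other tests were planned. Called sites were more often lower than higher in each knockout with each other threshold, filter, link rule or replicate tried. Testing again relative to the table medians removes a common shift by construction. It gave 1409 lower and 1797 higher sites for METTL3, 1603 and 1572 for METTL14, and 893 and 2037 for METTL16. The implied standard error is too small at sites with little change, which can inflate these higher counts. Of the named sites, 484 of 536 calls held at an adjusted p of 0.01 and 52 were lost; after centring 471 of 546 held, 36 were lost, 11 were gained and 28 reversed. Of the 10 list results, 9 held against matched genes, all but chromatin modifiers after METTL14 knockout. The centred list results count calls made against 0 by their sign relative to the median and do not test a difference from it.

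Centring the signs of the authors' calls left 3139 lower sites for METTL3 and 3462 for METTL14, gave 1195, 1028 and 820 higher sites for METTL3, METTL14 and METTL16, moved the shares lower to 72.5%, 74.1% and 72.1%, and let 17 list tests pass. Those that had not passed before were higher chromatin, eraser and reader, and U6 genes and lower ZNF genes after METTL14 knockout, higher eraser and reader and cell cycle genes after METTL3 knockout, and more higher writer and fewer higher ZNF genes after METTL16 knockout. Splicing factors after METTL14 knockout no longer passed. Among the sites it reversed were ADAR (0.23 METTL3, 0.04 METTL14), ALKBH5 (0.03 METTL3), CDKN1B (0.10 METTL3, 0.44 METTL16), CENPF (0.45), EIF3A (0.27), EIF4G1 (1.12 METTL3), H2AFX (0.38 METTL16, 1.12 METTL14), MALAT1 (1.17 METTL3, 1.10 METTL14), METTL14 (0.12), METTL16 (0.025 METTL3), PCIF1 (0.01 METTL3), RBM15B (0.26 METTL14, 0.20 METTL16), RPL28 (0.30), SESN2 (0.15), SOX2 (0.33), TUG1 (0.22 and 0.68), YTHDF1 (0.77 METTL3, 0.32 METTL14), ZC3H13 (0.56 METTL3, 0.14 METTL14) and ZFP36L2 (0.19), in METTL14 knockout where no name is given. Identical start and end left 1935, 1903 and 1057 lower and 88, 59 and 116 higher sites. A log2 change of at least 1 left 220, 81 and 124 higher sites, by construction.

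With 1 replicate left out, calls need 1 table only. METTL3 then had 556 to 734 higher sites, METTL14 508 to 676, and METTL16 4814 to 5508 lower and 1088 to 1100 higher. METTL16 shared 2859 to 2923 lower sites with METTL3 and 3559 to 3881 with METTL14, and 11 to 16 list tests passed. The share of lower sites near a stop codon was 27.9% to 28.3% for METTL3 and 27.2% to 28.3% for METTL14. The DRACH difference ranged from −1.64 to −0.83 for METTL3, from −1.48 to 0.05 for METTL14, reversing without replicate 1, and from −0.79 to −0.30 for METTL16; the cause was not tested. Taken by the 3′ end, 20.6%, 19.6% and 19.4% of lower sites were near a stop codon. Only 41.3%, 35.0% and 37.1% of uncalled sites held GGACT, so their median GGACT density was 0.0 for each knockout. Mean GGACT density was lower in lower sites, at 1.98, 1.96 and 1.77 copies per kb against 2.27, 2.15 and 2.09. Median GGACT density in lower sites thus exceeded that in uncalled sites by 1.43, 1.39 and 0.78, against negative DRACH differences. With peaks at an adjusted p of 0.05 or less in both tables these became 0.0 (adjusted permutation p 1.0), 1.46 (0.00356) and 0.95 (0.535).

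Adjusted over all sites, limma called 0 sites under every setting except a control without error, which gave 1937 lower and 175 higher for METTL3 and 1260 and 39 for METTL14, and made 93 and 159 false calls on simulated data. A replicate block in METTL16 minus METTL14 gave 0 lower and 0 higher, with 1195 at an unadjusted p under 0.05; replicate numbers did not pair the libraries (r −0.061 over 13218 sites). Depth is unknown, and the single control pair behind each table limits every count.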

Other observations

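The test of few reads behind the replicate correlations was chosen only after the result was seen, and so was the set of sites in which TACAGAGAA was sought; the motif test itself was written beforehand.

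METTL16 binds a hairpin whose loop holds TACAGAGAA in RNA letters, so this sequence was sought in the sites separated most between METTL16 and METTL14 knockout. The prediction concerned sites called by limma, of which there were 0, with 1727 of 13218 at an unadjusted p under 0.05, and it was applied instead to the 500 sites lowest in METTL16 relative to METTL14. Of these, 5 (1.0%) held the motif, against 47 of 11737 others (0.4%), an odds ratio of 2.51 (95% interval 0.78 to 6.33, Fisher's exact p 0.0602). The interval includes 1, the outcome named beforehand for no enrichment, but with 5 sites it also reaches 6.33 and so leaves an enrichment open. Among sites with the motif 18 of 55 were lower after METTL16 knockout, 19 of 47 after METTL3 knockout and 23 of 54 after METTL14 knockout. Over all linked sites 20.8%, 44.2% and 38.7% were lower, in the same order. The median site with the motif stood at −0.86 after METTL16 knockout, against −1.0 at other sites, and no difference in these shares was tested. MAT2A, with 4 copies, may be a site of its own kind in these data.

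Replicate tables of a knockout correlated across sites at r 0.577 for METTL3, 0.426 for METTL14 and 0.379 for METTL16, while unchanged knockouts sharing a control gave 0.5, 0.5 and 0.498 in simulation. Sites are not independent replicates. Few reads at weakly enriched sites could lower these values. Among the strongest peaks r was 0.508 for METTL14 and 0.457 for METTL16, against 0.417 and 0.355 among the others, and the smaller gain of 0.091 was too small to decide. Knockout libraries that vary more than the control would lower r as well, and counts per library, which would settle it, are not in the tables. No biological explanation was tested.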
